A study of Rattus norvegicus with 27 samples.

How the data were processed

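The data are 27 RNA-seq libraries of primary lung fibroblasts of Sprague-Dawley rats, an outbred laboratory stock. Per the labels' protocols, the fibroblasts were taken from lung by magnetic bead sorting for CD90, the Thy-1 surface antigen, and grown on plastic or on polydimethylsiloxane (PDMS), a silicone elastomer of 3 to 5 kPa. Both surfaces were coated with rat tail collagen I at 38 µg/ml. Libraries were made with an Illumina TruSeq kit from 200 ng of total RNA and read on a HiSeq2000. The labels put 4 libraries in each of PDMS day 2, PDMS day 4, PDMS day 7, PDMS day 14, Plastic day 4 and Plastic day 14, and 3 in Plastic day 7. They do not say which animal, cell isolation or culture a library came from, so p-values measure the spread between these libraries, part of which may be technical.

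The authors deposited raw counts per Ensembl rat gene ID, as whole numbers, in 1 column per library. Per the series design text, read quality was checked with FastQC 0.11.2 and duplicate reads were marked with bamUtil 1.0.11 and assessed with dupRadar 1.4. The same text says that expression was quantified with Cufflinks, which the submitters' processing notes give as version 2.2.1. The notes also name STAR and DESeq2, whose roles are not given in the sources used here. Which program made the deposited counts, its strand setting, the genome build and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies may have been shared or split. Tables of depth-scaled and of variance-stabilized values were not used here. Of the 28 columns of the count table, 1 belongs to no listed sample and was not used. The table names 32753 gene IDs, of which 11756 had no read in the 27 libraries, and it has 0 rows that name no gene.

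The files do not pair the gene IDs with names, and 0 of the 32753 IDs matched a symbol in the RefSeq table of the GRCr8 assembly that was at hand. The rule for named genes, fixed before the data were examined, took genes with a symbol, an adjusted p under 0.05, no overlap between the log2 CPM values of the groups and a mean of at least 5 CPM in the higher group, ranked by fitted fold change. It could not be applied as written. In its place 4 IDs are given, the 2 with the largest rise and the 2 with the largest fall under the rule without its symbol condition, for PDMS against plastic at day 7. That comparison was chosen for them after the data were seen. The 23 gene lists fixed before the data were examined (contractile, matrix, YAP/TAZ, TGF-beta, inflammatory, cell cycle, other cell types and more) are written as symbols. Their tests were not run, and no gene group is described by function.

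Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design (a count of about 10 in at least 3 libraries and a total of at least 15), which left 14258 genes holding at least 99.9% of each library's reads. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 27 libraries at once, with 20 residual degrees of freedom and a median biological coefficient of variation of 0.243. Contrasts were tested with the two-sided quasi-likelihood F test, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change over the square root of F. CPM is counts per M (mega) of the TMM-scaled library size, and log2 CPM carries a prior count of 2. The design, the 8 contrasts and the count of genes called at all 3 days were fixed before the data were examined. The mean of the substrate contrast over days 4, 7 and 14 and the interactions of day 7 against day 4 and of day 14 against day 7 were added after seeing the data.

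The spread of reads over genes was measured per library as the percent of reads in the top 10 genes, as the effective number of genes (the exponential of the Shannon entropy of the gene shares), and as the number of genes with at least 10 reads after thinning each library to 17285101 reads. Groups were compared on these by exact two-sided permutation tests, adjusted over 21 tests. Shares of variance are sums of squares of log2 CPM.

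Replicate numbers appear in the labels without a statement of what they mark. Deviations from the group means were correlated between libraries of the same number. For PDMS day 4 against PDMS day 2 all 4 pairs had a correlation over 0.1 (0.14 to 0.57). These were not set against pairs of other numbers in the same groups, so a pairing by number is possible there but was not shown. In the other contrasts at least 1 pair was below 0.1.

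The fit was tested on simulated counts, drawn independently for each gene and library with the means, dispersions and library sizes of the real genes, with 200 genes changed. For PDMS against plastic at day 7, among 14045 simulated genes tested, 42% of the genes changed 2-fold and 74% of those changed 4-fold were recovered, with 8 false calls. For day 4 these were 47% and 75%, and for day 14 52% and 74%. For the interaction of day 14 against day 4 they were 27% and 58%. Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter beyond 1 read, a filter of over 5 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), a fit of the contrasted groups alone, the replicate number as a block, and leaving out each library in turn.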

Results

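The series measured messenger RNA in primary rat lung fibroblasts kept on collagen-coated plastic or on collagen-coated soft PDMS for 2 to 14 days. The labels place the PDMS at 3 to 5 kPa and give no stiffness for plastic. The design asks how the transcriptome differs between the substrates at a given day and how it moves with days in culture. Totals ran from 17.3 to 25.3 M counts per library (M, mega). Mean totals were 20.1 ± 2.23 M for PDMS day 2 (SD, n = 4), 21.1 ± 0.86 for PDMS day 4 (n = 4), 21.6 ± 3.92 for PDMS day 7 (n = 4) and 23.5 ± 1.94 for PDMS day 14 (n = 4). They were 22.1 ± 1.06 M for Plastic day 4 (n = 4), 19.9 ± 2.12 for Plastic day 7 (n = 3) and 20.3 ± 1.42 for Plastic day 14 (n = 4).

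Days in culture set the main axis of the data. The first principal component of log2 CPM carried 45.8% of the variance and ordered the groups by day, from a mean score of -109.72 ± 37.18 at PDMS day 2 (SD, n = 4) to 75 ± 19.88 at PDMS day 14 (n = 4). Plastic day 14, at 70.2 ± 3.63 (n = 4), lay beside PDMS day 14. The second component, with 15.9%, spread libraries within groups. Over the 23 libraries of days 4, 7 and 14, day took 37.9% of the variance, substrate beside day 8.07% and their interaction 5.84%, and 48.2% was left between replicates. Part of each share comes from the spread between replicates, and the interaction share was not tested against that spread. The substrate share was larger than in most reassignments of the substrate labels within days (one-sided exact permutation p = 0.0133 over 171500 assignments). Within single days it was 13.8% at day 4, 41.0% at day 7 and 16.7% at day 14, with one-sided exact p of 0.314, 0.0286 and 0.286, and 0.314, 0.0858 and 0.314 after Benjamini-Hochberg adjustment over the 3 days.

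**Figure D1:**
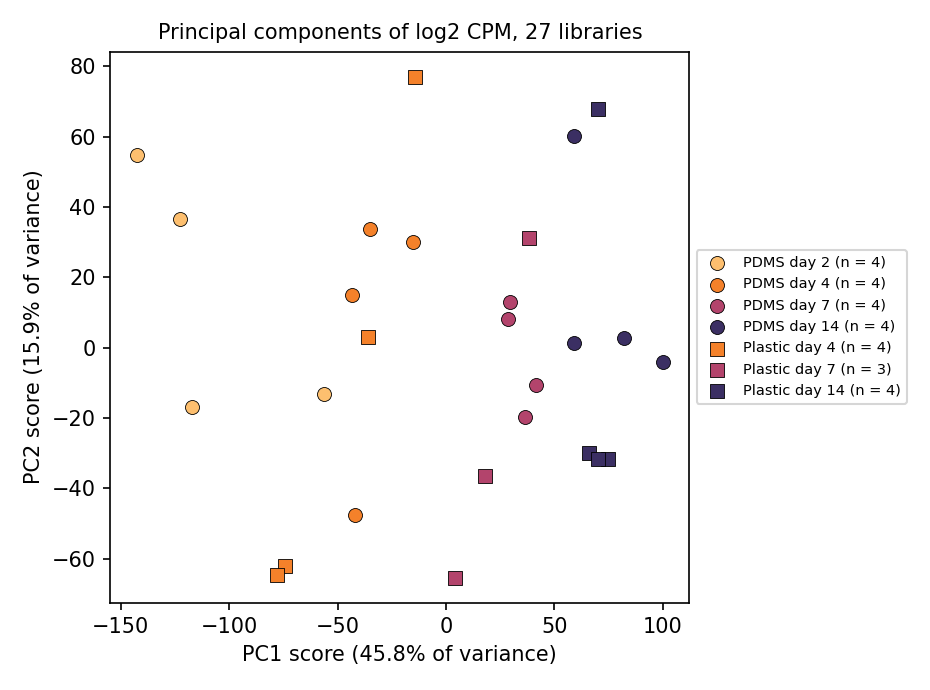
Scores of the 27 libraries on principal components 1 and 2 of log2 CPM (no unit). Circles are PDMS and squares plastic, with days by colour, and PDMS day 2 lies at the left end (mean PC1 -109.72) and both day 14 groups at the right end (75 and 70.2).

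On PDMS, 7358 of 14258 genes differed between day 14 and day 2, of which 3461 rose and 3897 fell (edgeR quasi-likelihood test, adjusted p under 0.05, n = 4 and 4). The called genes that rose had a median log2 fold change of 1.05 and those that fell one of -1.22, and 3984 changed more than 2-fold. Relative to PDMS day 2, the 3461 genes stood at a median log2 difference of 0.43 at PDMS day 4, 0.66 at day 7 and 1.06 at day 14. The 3897 genes stood at -0.45, -0.77 and -1.13. Choosing genes on the same day 2 libraries pushes all of these medians in the called direction. Steps between groups that share no library with that contrast avoid this. From PDMS day 4 to PDMS day 7 the mean log2 CPM of the 3461 genes moved by 0.31 and that of the 3897 genes by -0.67 (n = 4 and 4; two-sided exact permutation p = 0.0286 for each, 0.0429 after Benjamini-Hochberg adjustment over 6 tests added after seeing the data). On plastic they moved by 0.49 (exact p = 0.114, adjusted 0.114) and -0.64 (exact p = 0.0286, adjusted 0.0429) from day 4 to day 7 (n = 4 and 3). From day 7 to day 14 on plastic they moved by 0.33 (exact p = 0.114, adjusted 0.114; 0.18 without Plastic day 7 replicate 4) and -0.43 (exact p = 0.0286, adjusted 0.0429). The plastic libraries are outside the contrast that chose these genes, though they share its scaling, filter and error estimate and are set against the same PDMS day 2 libraries. They stood at 0.37, 0.70 and 0.98 and at -0.30, -0.69 and -0.98 at days 4, 7 and 14. The 4 libraries of each group did not overlap in 40.0% of genes, against 2.86% by chance. With library size in place of TMM, 35.9% of the calls were rises instead of 47%, and the median of all genes shifted from -0.05 to -0.20.

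**Figure D2:**
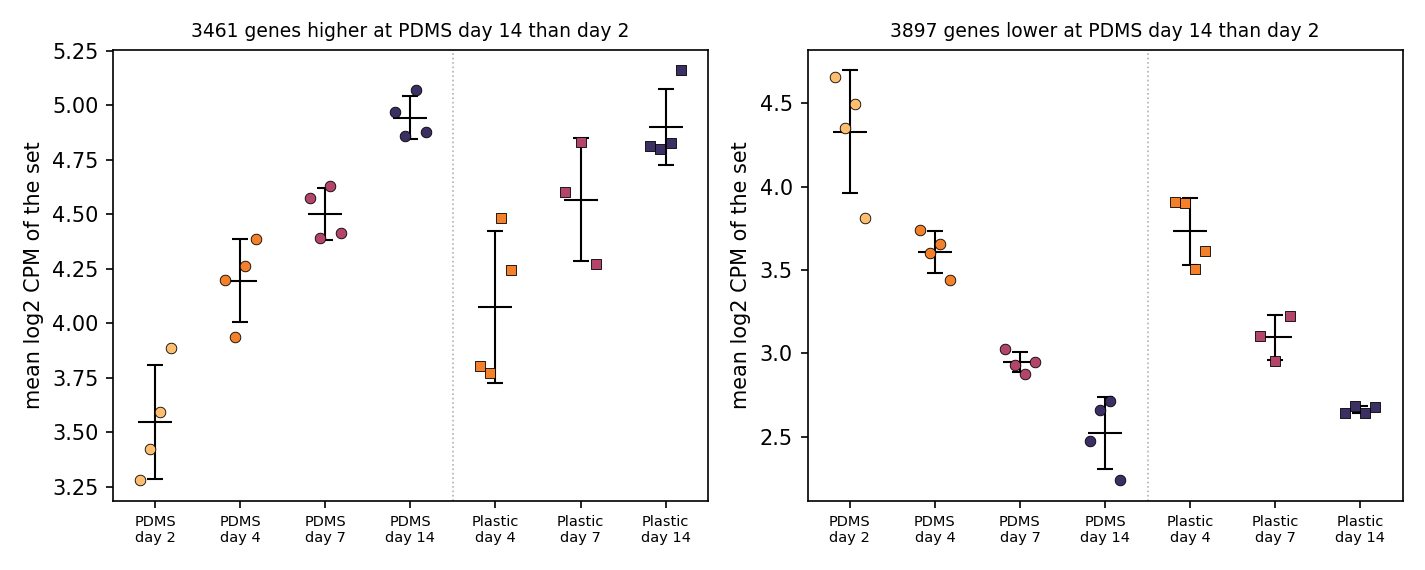
Mean log2 CPM per library of the 3461 genes that were higher (left) and the 3897 that were lower (right) at PDMS day 14 than at PDMS day 2. Points are libraries, bars the group mean and SD, and both substrates move from day 4 to day 14 in the same direction.

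Between day 2 and day 4 on PDMS, 1428 genes differed, 737 of them higher and 691 lower at day 4 (edgeR, n = 4 and 4), with median log2 fold changes of 1.09 and -1.46. Of all genes, 9.22% had groups that did not overlap. Leaving out 1 library moved this count by over 1.5 times in 7 of 8 cases. It was 56 without PDMS day 2 replicate 1, 757 without PDMS day 2 replicate 2, 489 without PDMS day 2 replicate 3, 3307 without PDMS day 2 replicate 4, 431 without PDMS day 4 replicate 1, 476 without PDMS day 4 replicate 3 and 238 without PDMS day 4 replicate 4, and it was 0 in a fit of these groups alone.

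From day 4 to day 14 the fibroblasts changed along a similar course on both substrates. On PDMS 1906 genes rose and 2169 fell (4075 in all), and on plastic 2038 rose and 2603 fell (4641 in all; edgeR, n = 4 per group). The median log2 fold changes of these genes were 0.78 and -1.21 on PDMS and 0.94 and -0.99 on plastic. No library was shared between these contrasts. Of the genes called, 1176 rose on both substrates, against 272 for independent lists, and 1431 fell on both, against 396. Only 2 genes were called in opposite directions, against 658 for independent lists. Of the 6107 genes called on either substrate, 95.3% had the same sign on both. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.81 and a Spearman rho of 0.79. On plain differences of mean log2 CPM r was 0.86, and no reassignment of the day labels within substrates exceeded it in size (two-sided exact permutation p = 0.000816 over 4900 assignments, the smallest they can give). The reassignments treat the libraries as independent, which the closely alike plastic pairs and library sets described below may undo.

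A test of the difference between these courses, the interaction of substrate with day 14 against day 4, called 0 genes with edgeR, 4 with DESeq2 and 0 with limma-voom. At an unadjusted p under 0.05 edgeR gave 971 genes where 713 are due by chance. The PDMS count fell to 2590 without PDMS day 4 replicate 1 and to 2617 without PDMS day 14 replicate 3, and the plastic count to 3075 without Plastic day 4 replicate 2. Summing 2 pairs of closely alike plastic libraries gave 2375 genes on plastic, and a fit of the plastic groups alone gave 2519. With library size in place of TMM, rises made up 32.1% of the calls on PDMS in place of 46.8%, and 27.1% on plastic in place of 43.9%, with the median of all genes moving from -0.03 to -0.15 and from -0.05 to -0.21.

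At day 7, 121 genes differed between the substrates, 100 of them lower and 21 higher on PDMS (edgeR, n = 4 and 3). The differences were uneven in size. The 100 genes had a median log2 fold change of -2.27 and the 21 genes one of 0.64, and 87 and 6 of them differed more than 2-fold. In all 121 genes the PDMS and plastic libraries did not overlap. Of all tested genes 18.3% did not overlap, against 5.71% by chance. The gene lists of contractile, matrix and YAP/TAZ genes fixed for this comparison could not be looked up by ID.

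Of the IDs given for this comparison, ENSRNOG00000029514 had the largest fall. It stood at 38.3 ± 33.7 CPM on plastic (SD, n = 3) and 0.60 ± 0.54 on PDMS (n = 4), a log2 fold change of -5.94 ± 1.35 (SE; edgeR adjusted p = 0.0398). ENSRNOG00000007067 stood at 6.66 ± 6.62 CPM on plastic and 0.14 ± 0.16 on PDMS, where its 4 libraries held 0, 1, 3 and 9 counts (log2 fold change -5.48 ± 1.32, edgeR adjusted p = 0.04999). ENSRNOG00000013092 was higher on PDMS, at 14.3 ± 3.07 CPM against 6.14 ± 1.60 (log2 fold change 1.22 ± 0.28, edgeR adjusted p = 0.0406). ENSRNOG00000004736 was also higher on PDMS, at 21.8 ± 2.06 CPM against 9.49 ± 0.23 (log2 fold change 1.20 ± 0.26, edgeR adjusted p = 0.0359). With time on PDMS, ENSRNOG00000013092 fell from 29.5 ± 7.91 CPM at day 2 to 8.22 ± 2.29 at day 14 (log2 fold change -1.84 ± 0.26, edgeR adjusted p = 1.5e-05) and ENSRNOG00000029514 from 25.2 ± 13.3 to 0.90 ± 1.24 (log2 fold change -4.79 ± 1.25, adjusted p = 0.00315). On plastic, from day 4 to day 14, ENSRNOG00000029514 fell from 57.2 ± 57.5 to 2.68 ± 2.26 CPM (log2 fold change -4.42 ± 1.20, adjusted p = 0.00857) and ENSRNOG00000007067 from 7.08 ± 6.12 to 0.65 ± 0.48 CPM (log2 fold change -3.43 ± 1.13, adjusted p = 0.0245). Among the Plastic day 4 libraries both were highest in replicates 1 and 2, a closely alike pair described below (104 and 109 CPM, and 12.8 and 11.6 CPM). Replicate 3 stood at 0.94 and 0.09 CPM and replicate 4 at 14.5 and 3.85 CPM. Over all libraries ENSRNOG00000007067 was highest in Plastic day 7 replicate 1 (13.9 CPM). Plastic day 7 replicates 3 and 4 held 1.03 and 5 CPM of it. None of the 4 IDs was called between the substrates at day 4 (lowest edgeR adjusted p = 0.418) or at day 14 (lowest adjusted p = 0.753). At day 4 the log2 fold change on PDMS was -2.89 ± 1.11 for ENSRNOG00000029514 (SE; edgeR adjusted p = 0.418), -2.27 ± 1.06 for ENSRNOG00000007067 (adjusted p = 0.547), 0.59 ± 0.25 for ENSRNOG00000013092 (adjusted p = 0.471) and 0.08 ± 0.23 for ENSRNOG00000004736 (adjusted p = 0.999). At day 14 it was -1.55 ± 1.16 for ENSRNOG00000029514, -0.60 ± 1.13 for ENSRNOG00000007067, 0.33 ± 0.25 for ENSRNOG00000013092 and 0.30 ± 0.23 for ENSRNOG00000004736. The signs are those of day 7, but the day 4 value of ENSRNOG00000004736 and the day 14 value of ENSRNOG00000007067 lie within 1 SE of 0.

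**Figure D3:**
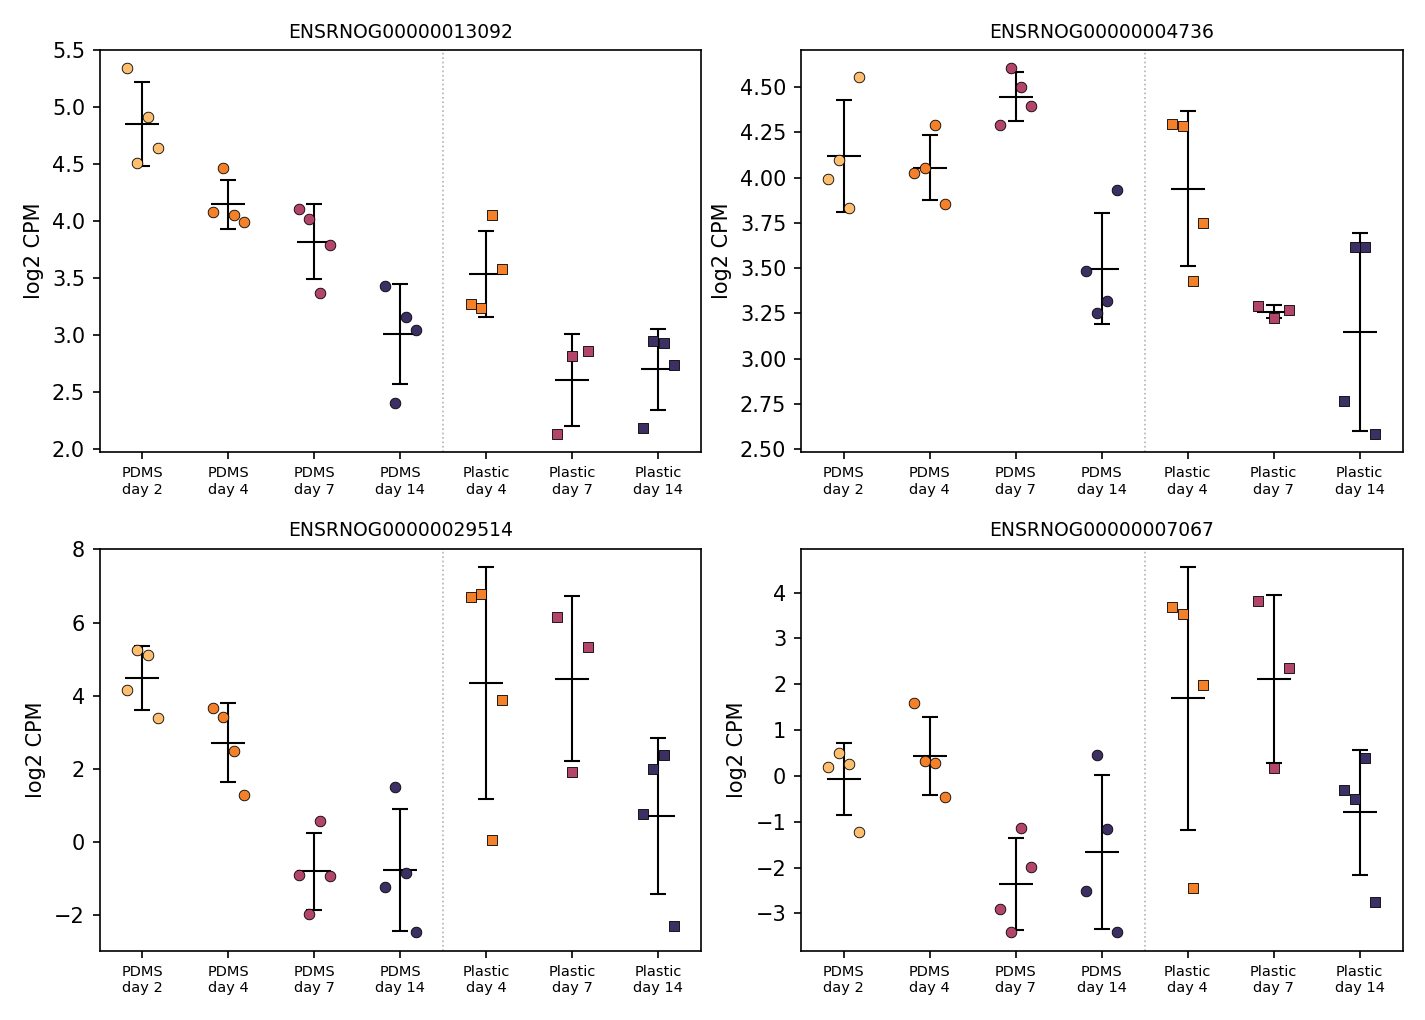
Log2 CPM per library of the 4 gene IDs in each of the 7 groups. Points are libraries and bars the group mean and SD; at day 7 the upper IDs are higher on PDMS (log2 fold change 1.22 and 1.20) and the lower IDs are lower on PDMS (-5.94 and -5.48).

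The day 7 calls lay close to the threshold (smallest adjusted p = 0.0274) and ended when any of 4 libraries was left out. No gene was called without Plastic day 7 replicate 1, or without PDMS day 7 replicate 1, 2 or 4 (0 genes each), and 31 were called without Plastic day 7 replicate 4 and 193 without Plastic day 7 replicate 3. In the 4 fits without a call, 1480 to 2374 genes had an unadjusted p under 0.05, and the log2 fold change was 1.18 to 1.29 for ENSRNOG00000004736, 1.02 to 1.24 for ENSRNOG00000013092, -5.14 to -5.80 for ENSRNOG00000029514 and -4.33 to -5.52 for ENSRNOG00000007067. The IDs were chosen for large folds without overlap on these libraries, so their folds are no separate evidence. DESeq2 called 781 genes, among them all 121 in the same direction, and limma-voom called 42. The called genes were 17.4% higher on PDMS, and 41.7% of the 60 genes called with library size in place of TMM, which moved the median of all genes from 0.01 to 0.13.

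The 100 genes lower on PDMS at day 7 were then followed in the libraries of days 4 and 14. These are outside the day 7 contrast, but share its scaling, filter and error estimate. Some also share library sets, described below, with day 7 libraries, and the tests that follow treat the libraries as independent. A fit of the day 7 groups alone called 74 of the 121 genes in the same direction among its 273. The mean log2 CPM of the 100 genes at day 4 was 3.20 ± 0.26 on PDMS and 4.13 ± 0.74 on plastic (SD, n = 4 each; two-sided exact permutation p = 0.0571), and 95 of them had lower fitted levels on PDMS. Plastic day 4 replicates 1 and 2, a closely alike pair, stood at 4.66 and 4.69. Plastic day 4 replicate 3, at 3.11, lay within the PDMS day 4 range of 3.04 to 3.58. At day 14 the mean of the 100 genes was 2.11 ± 0.48 on PDMS and 2.82 ± 0.05 on plastic (n = 4 each; exact p = 0.0286), and 92 were lower. The 21 genes stood at 5.01 ± 0.09 on PDMS and 4.84 ± 0.08 on plastic at day 4 (n = 4 each; exact p = 0.0286) and at 4.85 ± 0.10 and 4.68 ± 0.10 at day 14 (exact p = 0.0571). After Benjamini-Hochberg adjustment over these 4 tests each was 0.0571, and the smallest p that 4 against 4 libraries can give is 0.0286. With time, 59 of the 100 genes fell and 5 rose from day 4 to day 14 on plastic, and 42 fell and 6 rose on PDMS (edgeR). Of all 14258 genes, 2603 fell and 2038 rose on plastic, and 2169 fell and 1906 rose on PDMS.

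**Figure D4:**
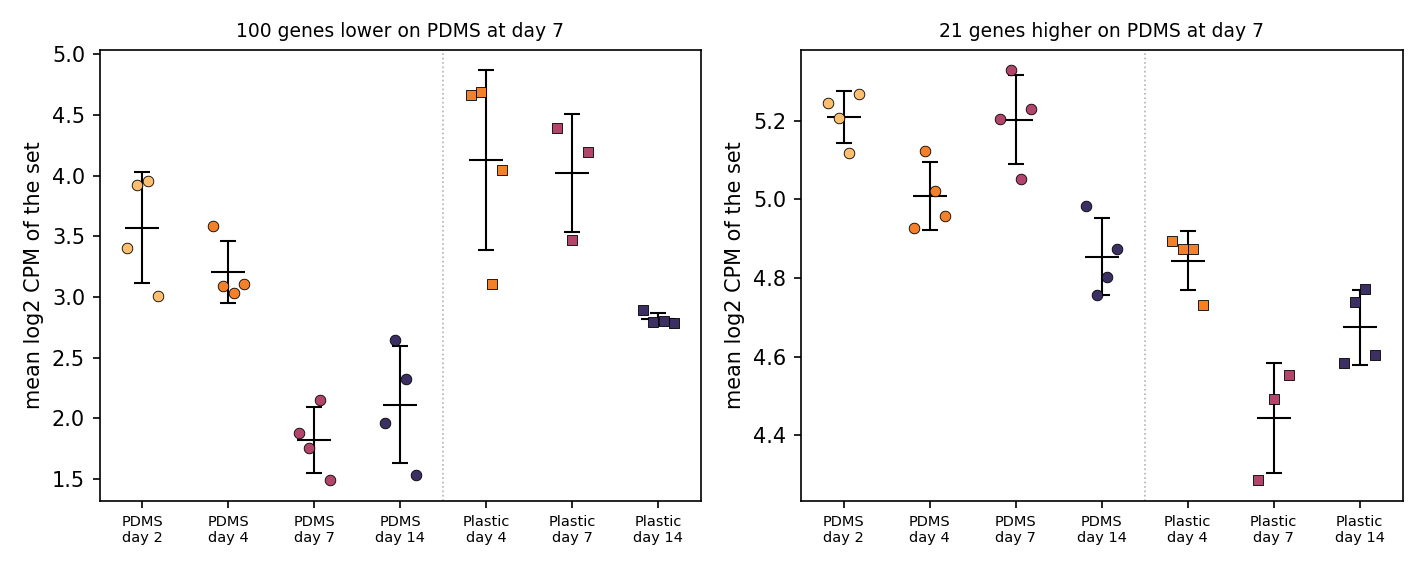
Mean log2 CPM per library of the 100 genes called lower (left) and the 21 called higher (right) on PDMS at day 7. Points are libraries, bars the group mean and SD; the sets were chosen on the day 7 groups, and at days 4 and 14 the group means lie in the same direction.

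At day 4, 0 genes passed between PDMS and plastic with edgeR (n = 4 and 4), 24 with DESeq2 and 0 with limma-voom. At an unadjusted p under 0.05 edgeR gave 1246 genes, 910 of them lower on PDMS, where 713 are due by chance. Without Plastic day 4 replicate 3 the count was 245, of which 209 were lower on PDMS. At day 14, 0 genes passed with edgeR (n = 4 and 4; smallest adjusted p = 0.0594), 113 with DESeq2 and 2 with limma-voom, and 1266 had an unadjusted p under 0.05. Without Plastic day 14 replicate 4 the count was 88, without PDMS day 14 replicate 2 it was 6, and with library size in place of TMM it was 8. Accordingly, 0 genes were called at all 3 days in the same direction with edgeR and with limma-voom, and 1 with DESeq2.

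The day 7 difference was not shown to be larger than that of another day. The interactions of substrate with day 7 against day 4 and with day 14 against day 7, added after seeing the data, called 0 genes each with edgeR. At an unadjusted p under 0.05 they gave 419 and 980 genes, where 713 are due by chance. DESeq2 called 0 and 1, and limma-voom 0 and 0. Without PDMS day 7 replicate 3 each called 1 gene with edgeR.

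Reads became concentrated in fewer genes from day 4 to day 14 on both substrates. By the effective number of genes and the top 10 share they were more concentrated on plastic at days 7 and 14. The count of genes with at least 10 reads leaned the other way at those days, with fewer on PDMS. The effective number of genes was 4061 ± 359 at PDMS day 2 (SD, n = 4), 3892 ± 125 at PDMS day 4 (n = 4), 3704 ± 179 at PDMS day 7 (n = 4) and 3337 ± 86 at PDMS day 14 (n = 4). On plastic it was 3664 ± 299 at day 4 (n = 4), 3093 ± 418 at day 7 (n = 3) and 2937 ± 85 at day 14 (n = 4). From day 4 to day 14 it changed by -555 on PDMS and by -728 on plastic (two-sided exact permutation p = 0.0286, adjusted 0.0462 for each). The change of -169 from PDMS day 2 to PDMS day 4 did not pass (exact p = 0.543, adjusted 0.543). It was 9.75 without PDMS day 2 replicate 2. PDMS was above plastic by 611 genes at day 7 and by 400 at day 14, with no overlap between the libraries (two-sided exact permutation p = 0.0286 for each, 0.0462 after Benjamini-Hochberg adjustment over 21 tests). Without Plastic day 7 replicate 1 the day 7 difference was 373. At day 4 the difference of 227 did not pass (exact p = 0.257, adjusted 0.3), and it was 108 without Plastic day 4 replicate 4. The top 10 genes took 9.29% ± 0.30 of reads at Plastic day 14 and 8.17% ± 0.40 at PDMS day 14 (n = 4 each; exact p = 0.0286, adjusted 0.0462). The number of genes with at least 10 reads after thinning fell on PDMS from 13125 ± 195 at day 2 to 12414 ± 222 at day 14 (n = 4 each; exact p = 0.0286, adjusted 0.0462), and PDMS minus plastic was 80.8 genes at day 4 (n = 4 each; exact p = 0.2, adjusted 0.262; 52.8 without PDMS day 4 replicate 1), -155 at day 7 (n = 4 and 3; exact p = 0.0857, adjusted 0.129) and -121 at day 14 (exact p = 0.429, adjusted 0.474; -12.8 without PDMS day 14 replicate 4).

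**Figure D5:**
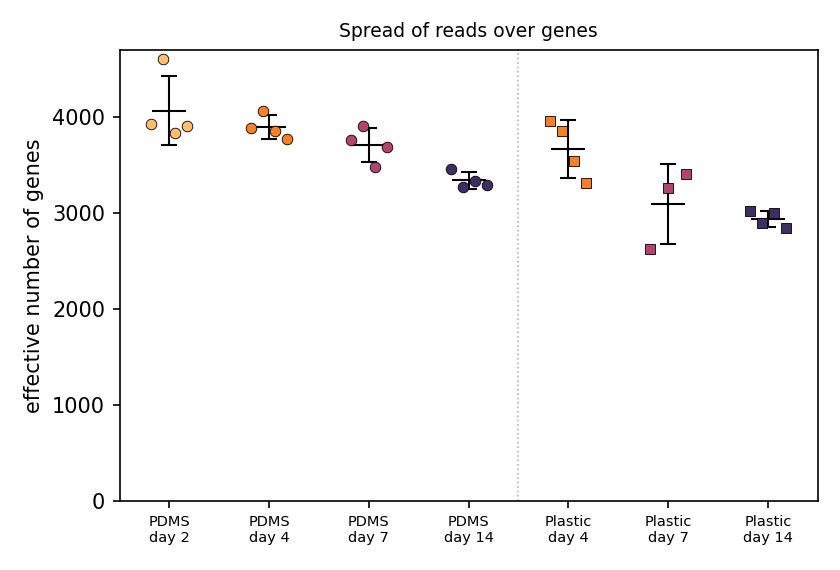
Effective number of genes per library (exponential of the Shannon entropy of the gene shares of reads) in the 7 groups, on an axis from 0. Points are libraries and bars the group mean and SD; Plastic day 14 (2937) lies below PDMS day 14 (3337).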

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

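The tests of explanations here were chosen after the results were seen. A library was marked when its gap to the nearest of the other 3 took up most of its group's range, by Dixon's criterion. Of 84 groups tested over 14 measures, 8 gave a mark, where chance gives about 4.2.

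PDMS day 14 replicate 3 held 20.6 M counts (M, mega), and the others of its group 24.2 to 24.7 M. PDMS day 2 replicate 2 had an effective number of genes of 4596, above 3825 to 3923 in the others. On the second principal component PDMS day 14 replicate 3 scored 60.2, with the others of its group between -4.08 and 2.78, and Plastic day 14 replicate 4 scored 67.9, with the others between -31.77 and -29.97. Plastic day 14 replicate 4 was also high for the genes that rose with time on PDMS, at a mean log2 CPM of 5.16 against 4.80 to 4.83. For the 100 genes lower on PDMS at day 7, PDMS day 4 replicate 1 stood at a mean log2 CPM of 3.58, above 3.04 to 3.11, and Plastic day 14 replicate 1 at 2.89, above 2.78 to 2.80. For the 21 genes higher on PDMS at day 7, Plastic day 4 replicate 4 stood at 4.73, below 4.87 to 4.89.

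The 121 calls between PDMS and plastic at day 7, against 0 at days 4 and 14, were weighed as a pattern. The values argue against scaling as the source of the folds: with library size alone, which moved the median of all genes from 0.01 to 0.13, the 100 lower genes had a median of -2.15 with a median SE of 0.50, in place of -2.27 with 0.49, each with an unadjusted p under 0.05, and with DESeq2 size factors it was -2.30. The 21 higher genes had 0.75 and 0.62 in place of 0.64. The number of calls did depend on scaling. It was 60 with library size alone (50 of them among the 121; 0 and 8 at days 4 and 14) and 163 with DESeq2 size factors (0 and 0). The smallest adjusted p of the 121 genes rose from 0.0274 to 0.0461 with library size alone, so calls close to the threshold ended at nearly the same fold. Day 7 had the most genes under each scaling, but its own count with 1 library left out reached 0, so how far the number of calls rests on scaling stays open. A second candidate explanation is that the day 7 libraries come from different sets of animals or cell isolations, as the genes with 2 separate levels might mark them, described among the other observations. With those library sets as a block, 0 genes were called. The median of the 100 lower genes was -2.12 with a median SE of 0.65, in place of -2.27 with 0.49. PDMS day 7 replicates 1, 2 and 4 formed a set of their own, so the block left replicate 3 alone to set the PDMS level. The 21 higher genes went from a median of 0.64 to 0.46, and residual degrees of freedom from 20 to 12. All 121 genes kept their sign with the block. That cannot decide, since the genes were chosen on these libraries with no overlap between the substrates. Of the library sets at day 7 only 1 held both substrates, so substrate and set cannot be told apart for these genes. An effect of the substrate stays open as well.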

How the results depend on the processing

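The alternatives of the closely alike pairs and the library sets, and every setting of the mean over days and of the added interactions, were chosen after seeing the data; the cause of a change was not tested unless stated. PDMS day 14 against day 2 (7358 genes) stayed within 1.5 times in every setting (5337 to 8543). For PDMS against plastic at day 7 (121 genes) the count was 60 with library size alone, 75 with no filter, 80 with the stricter filter, 781 with DESeq2, 42 with limma-voom, 273 in the fit of these groups alone, 35 with the close pairs summed and 0 with the library sets as a block. At day 4 (0) it was 24 with DESeq2. At day 14 (0) it was 8 with library size alone, 113 with DESeq2, 2 with limma-voom, 2 with the replicate block and 12 with the library sets. PDMS day 4 against day 2 (1428) gave 2414 with DESeq2, 0 in the fit of these groups alone and 4916 with the library sets. With the library sets PDMS day 14 against day 4 (4075) gave 6615, and plastic day 14 against day 4 (4641) 7168; the latter gave 2519 in the fit of these groups alone and 2375 with the close pairs summed. The interaction of day 14 against day 4 (0) gave 4 with DESeq2 and 16 with the library sets, that of day 14 against day 7 (0) 1 with DESeq2, and the genes called at all 3 days (0) 1 with DESeq2. The mean over days (1004) gave 1625 with library size alone, 1539 with DESeq2, 529 with limma-voom, 485 with the close pairs summed and 110 with the library sets. Leaving out 1 library at a time gave 0 to 193 genes at day 7, 0 to 245 at day 4, 0 to 88 at day 14, 56 to 3307 for PDMS day 4 against day 2, 6403 to 7258 for PDMS day 14 against day 2, 2590 to 3848 for PDMS day 14 against day 4, 3075 to 5319 on plastic, 434 to 1423 for the mean over days, 0 to 0 for the interaction of day 14 against day 4 and for all 3 days, and 0 to 1 for each added interaction. The 4 IDs kept their direction in every setting, which their choice for large folds without overlap on these libraries favours. Their adjusted p ran from 0.00367 to 0.536 for ENSRNOG00000013092, 0.00111 to 0.192 for ENSRNOG00000004736, 0.00011 to 0.31 for ENSRNOG00000029514 and 0.00111 to 0.331 for ENSRNOG00000007067, which the stricter filter removed. With the replicate block the counts were 165 at day 7, 0 at day 4, 1687, 7511 and 4421 on PDMS in the order above, 4879 on plastic, 0 for the interaction of day 14 against day 4 and 1039 for the mean; at day 14 it moved 0 to 2 and changed no other call by over 1.5 times. The numbers were not shown to pair the samples. Over 78 same-number pairs the mean correlation of deviations was 0.06 (-0.57 to 0.76), against -0.02 for pairs of other numbers across groups. Of 27 libraries, 10 correlated best with one of their own number. Neither value was tested against chance. The 23 gene list tests and their alternatives were not run, for want of symbols. At these totals the self-test recovered 42% to 52% of 2-fold changes between substrates within days, so small differences at days 4 and 14 were not detectable for many genes. Its libraries were drawn independently, without the library sets and close pairs described below, so these rates may not carry over to the real libraries.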

Other observations

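The mean over days, the alternatives and the tests in this part were chosen after the results were seen. Averaged over days 4, 7 and 14, 1004 genes differed between the substrates, 232 of them higher and 772 lower on PDMS (edgeR, 12 PDMS and 11 plastic libraries). The lower genes had a median log2 fold change of -1.17 and the higher ones of 0.33, and 440 of the lower and 21 of the higher genes differed more than 2-fold. The 4 IDs chosen at day 7 were all among them (edgeR adjusted p = 0.00783 to 0.0245), with the day 7 libraries that chose them part of this mean. Of the 100 reassignments of the substrate labels within days, the real one included, 1 gave as many genes, and the highest other count was 77. That argues against an arbitrary division of these libraries as the source of the count. The reassignments treat the libraries as independent, so they do not exclude a part for the library sets and close pairs described below. The balance of directions depended on scaling: 23.1% of the called genes were higher on PDMS with TMM, and 62.5% of the 1625 called with library size alone, which moved the median of all genes from 0.01 to 0.11. Of the 1004 genes, 838 were called in the same direction with both. The count was 434 without Plastic day 7 replicate 1, 636 without Plastic day 4 replicate 2, 627 without PDMS day 4 replicate 3, 625 without PDMS day 7 replicate 4 and 668 without PDMS day 14 replicate 4, and 110 with the library sets described next as a block.

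In 15 genes the libraries fell into 2 separate levels, with a gap of at least 2 on the log2 CPM scale, at least 3 libraries on each side and both levels present within at least 3 groups. If the replicate number marked the animal or isolation, libraries of the same number would share their levels across groups. They shared 62.3% of them, and libraries of other numbers 63.2% (one-sided permutation p = 0.653 over 10000 shuffles of the numbers), which argues against the number as the source of these levels. A candidate explanation is a small number of animals or cell isolations spread over the groups under changing numbers. It needs many library pairs alike, and 30 of 351 shared the level of every one of the 15 genes, 24 of them across groups. In 1000 shuffles of the levels within groups the mean was 0.83 such pairs and the highest 6, but the shuffles treat the genes as independent. Genes regulated together would give such pairs as well, and 3 pairs of these genes were on in the same libraries but for at most 2, so the count does not decide between the explanations. Allowing 1 gene to differ gave 9 library sets of up to 6 libraries; PDMS day 14 replicate 3 and Plastic day 14 replicate 4, which stood apart on the second principal component, were in 1 set. No animal is named in the labels, and inherited differences, sex, age and isolation batch were not tested.

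With these sets as a block, the counts over time rose from 1428 to 4916 genes for PDMS day 4 against day 2, from 4075 to 6615 for PDMS day 14 against day 4 and from 4641 to 7168 on plastic, while substrate counts fell from 121 to 0 at day 7 and rose from 0 to 12 at day 14.

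Within groups, 2 pairs of libraries were far closer than the rest: Plastic day 4 replicates 1 and 2, and Plastic day 14 replicates 2 and 3. Their counts differed by a mean chi-square per gene of 8.27 and 8.70, against 34.6 for the next of 39 within-group pairs and a median of 140.3, over genes with at least 50 reads in the pair. Counting noise alone gives about 1, which argues against 1 library entered under 2 names, and they were kept as separate replicates. Cells of the same animal or isolation could give such pairs, and both pairs were alike in all 15 genes, but 6 within-group pairs were, so this test does not decide. The others of these 6 had a chi-square per gene of 34.6 to 51.4, also below the median. With each of the 2 closest pairs summed to 1 library, the day 7 count was 35 and the plastic count 2375.

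Other splits of the same libraries were counted for each contrast. For PDMS against plastic at day 7, 1 of 35 splits, the real one, gave 121 genes and the highest other gave 9. That argues against an arbitrary division of the libraries as the source. It is the smallest share that 35 splits can give and was not adjusted over the contrasts. The splits also treat the libraries as independent, which shared animals or isolations would undo. The same holds for PDMS day 14 against day 2 (1 of 35; 7358 genes, highest other 1948), for PDMS day 14 against day 4 (1 of 35; 4075, highest other 18) and for plastic day 14 against day 4 (1 of 35; 4641, highest other 1706). For PDMS day 4 against day 2 an arbitrary division remains open: 2 of 35 splits gave at least 1428 genes, and the highest other, 1906, set PDMS day 2 replicate 4 with PDMS day 4 replicates 1, 3 and 4. Of the 8 splits that part all 4 same-number pairs, the real one had the most, and the highest other had 242. A pairing by number was not shown, so these splits do not settle it. At day 4 and day 14 the real splits gave 0 genes, which every split matches (35 of 35), so nothing about chance can be read from them. At each of these days 2 of the other splits gave any genes: 511 and 81 at day 4, and 457 and 5 at day 14. The highest of each points to a structure of the samples in those libraries, whose source was not tested. The counts of 0 for the interactions of day 14 against day 4, day 7 against day 4 and day 14 against day 7 and for the genes called at all 3 days are likewise matched by all 100 of 100 reassignments and cannot be judged this way. Their highest others were 964, 417, 518 and 0, and 3, 6, 12 and 0 of the other reassignments gave any genes.

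Substrate differences correlated across genes between days, without shared libraries: r was 0.56 for days 4 and 7, 0.40 for days 7 and 14 and 0.20 for days 4 and 14 (rho 0.50, 0.29 and 0.12). Genes are not independent replicates, and reassigning the substrate labels within both days gave two-sided exact permutation p of 0.0588, 0.139 and 0.405 (0.176, 0.209 and 0.405 after adjustment over the 3 relations), so none passed.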
